A study of Mus musculus with 6 samples.

How the data were processed

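The data are 6 Affymetrix Mouse Gene 2.0 ST arrays of splenic CD4+ T cells, 3 from cells kept with 100 µM icilin and 3 from cells kept with the solvent. Per the series design text, samples came from 3 mice and both groups from the same mice; the text does not say that a replicate number names a mouse, so the numbers were not used as pairs in the comparison itself. Each labelling reaction started from 0.25 µg of RNA with an integrity number of at least 8. The deposited table holds log2 values that the authors made with the RMA method, per the series design text, which covers background correction, normalization between arrays and summarising of probes into probe sets. It also states the study's test, significance analysis of microarrays (SAM) with limits of 1.5-fold and a false discovery rate of 0.1. No step of this processing was redone. The values were in the range of a log2 scale, with array medians between 4.24 and 4.30. RMA makes the distributions of the arrays alike, so a change common to most genes would not show, and log2 fold changes of dim genes are compressed toward 0.

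The value table has 41345 probe sets. The array annotation gave 1 gene symbol to 23521 of them, several to 1814 and none to 16010. The comparisons used the first kind, and where a gene had more than 1 probe set (1082 genes) the brightest over all 6 arrays was kept, leaving 22180 genes. The genome build of the array annotation was not given in the sources used here. A RefSeq annotation table (assembly GRCm38.p6) was used for gene names and for which genes are neighbours, and no coordinates are reported.

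Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with 1 prior variance, no trend and not robust; 4 residual and 3.07 prior degrees of freedom), icilin minus vehicle, two-sided, and p-values were adjusted by the Benjamini-Hochberg method over all 22180 genes. A gene counts as changed, or called, at an adjusted p under 0.1 and a change of at least 1.5-fold, the limits of the study. A test by permutation of 3 against 3 arrays cannot give a p under 0.1 for a single gene, whereas limma pools the spread over genes. Errors are SE of the log2 fold change from limma, and SD of 3 arrays beside group means. Gene lists were tested with camera from limma (preset correlation 0.01), adjusted over 35 lists, at 0.05, and again with a correlation estimated for each list. With the preset correlation 15 lists passed, 7 up and 8 down, and 2 passed with the estimated one. The rotation test fry, which does not compare a list with other genes, called 18 lists in 1 direction and 30 for change in either direction.

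The 35 lists hold 729 genes (653 measured, 41 on more than 1 list, 47 called) and cover T cell states, cytokine programmes, cell cycle, metabolism, stress responses, signalling targets, 6 sets of markers for other cell types and reference genes. The lists, the tests, the alternatives and the rule for naming genes were fixed before the data were examined. The rule named the 12 called genes with the largest rise and the 12 with the largest fall whose groups do not overlap, leaving out predicted genes, small RNAs, olfactory and vomeronasal receptors and antigen receptor segments. It also named up to 4 called members of each list by size of change (where none was called, the member with the smallest p), and Trpm8 and Trpa1. This gave 72 genes. Of the 311 called genes, 29 have names of the kinds left out.

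The alternatives were the replicate number as a block, an intensity trend with robust variances, centring each array on its median, quantile normalization, leaving out genes dimmer than the median, averaging all probe sets of a gene, leaving out each array in turn, SAM (20 permutations unpaired, 8 sign flips with the block), an adjusted p under 0.05 with no fold limit or with 2-fold, a fit over every probe set, and for lists an estimated correlation and fry. SAM was written anew for this work and was tested on simulated data together with limma and camera. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Probe sets with several symbols or none were left out of the comparisons, since their signal has no single gene to belong to.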

Results

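Gene expression was measured in CD4+ T cells isolated from the spleens of female C57BL/6 mice. The cells had been stimulated for 24 h through CD3 and CD28, the T cell receptor complex and its costimulatory receptor, and were then kept for another 24 h with 100 µM icilin or with the solvent dimethyl sulfoxide. Icilin is a synthetic cooling compound that opens the cation channels TRPM8 and TRPA1. Each group held 3 arrays, and both groups came from the same 3 mice. Expression of 22180 genes was compared between the groups. The small number of arrays limits precision: the median standard error of a log2 fold change was 0.09. Across genes, which are not independent replicates, arrays of the same group correlated at r of 0.990 to 0.991 and arrays of different groups at 0.989 to 0.990. The first principal component, with 38.7% of the variance, placed the icilin arrays at -15.4 to -14.6 and the vehicle arrays at 13.9 to 16.0.

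More genes were lower than higher with icilin. Of 22180 genes, 311 changed by at least 1.5-fold at a limma adjusted p under 0.1, and 229 of them fell (73.6%) while 82 rose. Over 2-fold, 69 genes fell and 18 rose. Without the fold limit, 1170 genes passed the same adjusted p, 666 lower and 504 higher, and the median log2 fold change over all genes was 0.01. In all 311 called genes the 3 icilin arrays lay entirely above or entirely below the 3 vehicle arrays. Such separation was seen in 5350 genes (24.1%), where chance gives 10%. The largest fall was that of Tgfb3, a transforming growth factor beta ligand, from a log2 level of 6.32 ± 0.24 (SD, n = 3) to 4.12 ± 0.25, a log2 fold change of -2.20 ± 0.16 (SE; adjusted p = 0.00126). The early response gene Ier3 dropped from 9.20 to 7.16 (-2.04 ± 0.10), and the transglutaminase gene Tgm2 from 10.6 to 8.89 (-1.76 ± 0.10). Other strongly lowered genes were Kremen2, a receptor for Dickkopf proteins (-2.08 ± 0.14), Fam183b (-2.06 ± 0.21), Ramp3, a partner of calcitonin-family receptors (-1.78 ± 0.10), and the heparan sulfate proteoglycan gene Sdc4 (-1.77 ± 0.18). They were followed by the tubulin gene Tubb6 (-1.75 ± 0.09), the acyltransferase gene Mboat2 (-1.69 ± 0.12), the cytokine gene Il24 (-1.61 ± 0.10) and the secreted peptide hormone genes Adm (-1.60 ± 0.13) and Stc1 (-1.59 ± 0.17). The largest rise was that of Trat1, an adaptor of the T cell receptor complex, from 7.73 ± 0.08 to 9.45 ± 0.04, which is 3.29-fold (adjusted p = 0.000623). Genes for transporters and a folate enzyme rose as well: the cystine transporter gene Slc7a11 by 1.60 ± 0.11, the mitochondrial folate enzyme gene Aldh1l2 by 1.47 ± 0.12 and the cationic amino acid transporter gene Slc7a3 by 1.16 ± 0.06. A second, dim probe set of Slc7a11 differed by 0.06, and with both probe sets averaged the gene rose by 0.83. The interferon-inducible genes Ifi209 (1.36 ± 0.14) and Gbp10 (1.32 ± 0.07) and the membrane protein genes Ms4a4b (1.28 ± 0.07) and Ms4a1 (1.01 ± 0.10) also rose. So did the reductase gene Cyb5r2 (1.27 ± 0.20), the adhesion receptor gene Selp (1.14 ± 0.11), Tnfrsf26 (1.13 ± 0.07) and the pseudokinase gene Trib2 (1.02 ± 0.07).

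**Figure D1:**
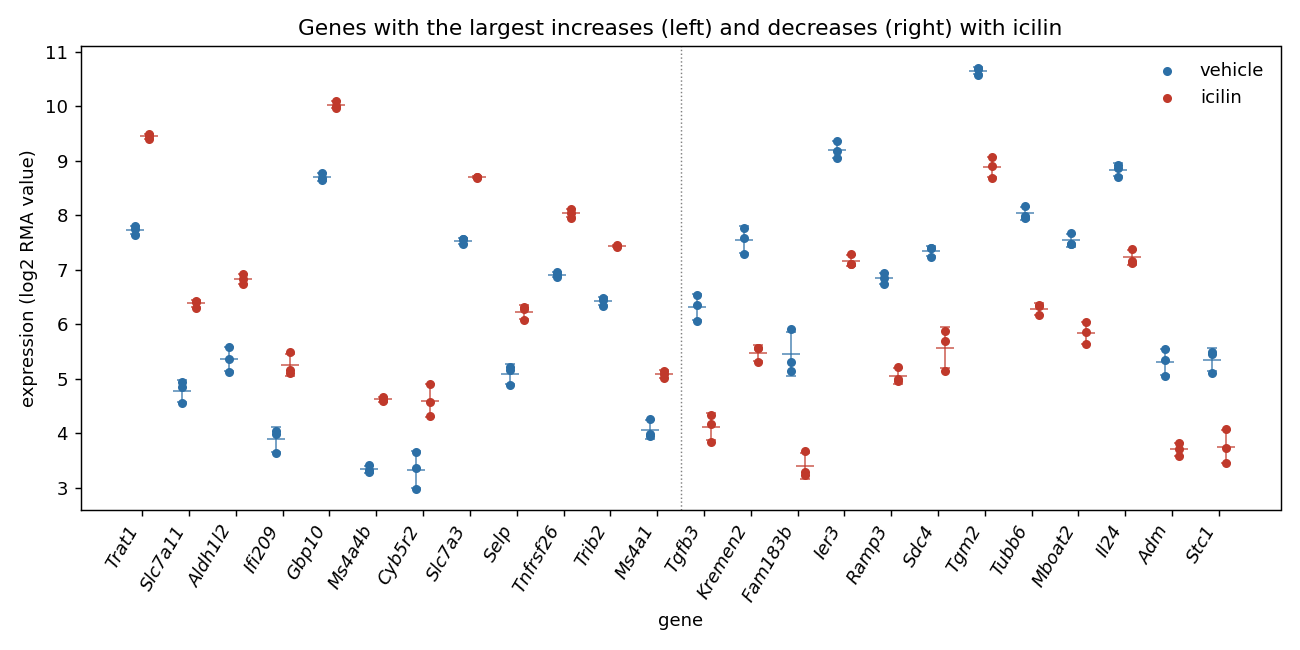
Log2 RMA level on each array (points; vehicle blue, icilin red) for the 12 most increased and the 12 most decreased named genes, with lines at the group means and bars for the SD of 3 arrays. The groups are separate for every gene shown, as the choice of genes required, from Trat1 (7.73 against 9.45) to Tgfb3 (6.32 against 4.12).

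The known receptors of icilin did not pass the test. Trpm8 had a log2 level of 3.59 in both groups (0.00 ± 0.06, adjusted p = 0.997), and Trpa1 stood at 2.77 in vehicle and 2.70 in icilin arrays (-0.06 ± 0.15, adjusted p = 0.870). Both lay in the dimmer part of the array, at brightness percentiles 32.1 and 17.2 of all genes, and both signs turned with single arrays left out (Trpm8 -0.02 to 0.04, Trpa1 -0.18 to 0.07). Among 22 measured genes of calcium entry and export, 1 fell, the plasma membrane calcium pump gene Atp2b4 (-0.90 ± 0.17, adjusted p = 0.0424), and 21 did not pass; the list as a whole had an adjusted p of 0.991 by camera. The call of Atp2b4 ended without icilin replicate 2 or without any 1 of the vehicle replicates (-0.93 to -0.86, adjusted p 0.113 to 0.145).

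Genes of glycolysis and the hypoxia response were lower as a group. Of 31 measured genes, 8 fell, 8 also when adjusted over the list alone, and 29 had a log2 fold change below 0, with a median of -0.33. The 4 with the largest falls were the hypoxia-induced gene Ndrg1 (-1.42 ± 0.08), the collagen prolyl hydroxylase gene P4ha2 (-1.38 ± 0.12), the aldolase gene Aldoc (-1.11 ± 0.12) and the glucose transporter gene Slc2a3 (-1.03 ± 0.07, from 11.4 to 10.4). The other 4, named after their values were seen, were the mitophagy receptor gene Bnip3 (-0.99), Mxi1 (-0.77), the oxygen-sensing hydroxylase gene Egln3 (-0.69) and the lactate exporter gene Slc16a3 (-0.62). Chosen in the same way, Hif1a, which encodes the oxygen-regulated subunit of hypoxia-inducible factor, had a difference of 0.13 (adjusted p = 0.328), and Slc16a1, a second lactate transporter gene, one of 0.28 (adjusted p = 0.0589). The list passed camera with an adjusted p of 1.89e-20, and with an adjusted p = 0.0346 with an estimated correlation.

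Targets of ATF4, the transcription factor of the amino acid response, were higher as a group. Of 34 measured genes, 9 rose, 9 also when adjusted over the list alone, and 30 had a log2 fold change above 0, with a median of 0.28. Besides Slc7a11 and Slc7a3, the largest rises were those of Trib3, an inhibitory pseudokinase gene (1.00 ± 0.07, adjusted p = 0.00105), and Cth, the last enzyme of cysteine synthesis (1.00 ± 0.07, adjusted p = 0.00126). The remaining 5, named after their values were seen, were the glutathione-degrading enzyme gene Chac1 (0.77) and the regulator genes Cebpb (0.76), Atf5 (0.72), Ddit3 (0.65) and Nupr1 (0.60). Without the fold limit, 19 members passed the adjusted p higher and 2 lower. The 2, also named after their values were seen, were Vldlr (-0.56, adjusted p = 0.0128) and Ddit4 (-0.42, adjusted p = 0.0207). For the list, camera gave an adjusted p of 4.80e-15 and an adjusted p = 0.0346 with an estimated correlation. Of the 35 lists tested, 15 passed camera, and these 2 were the ones that passed in both ways.

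**Figure D2:**
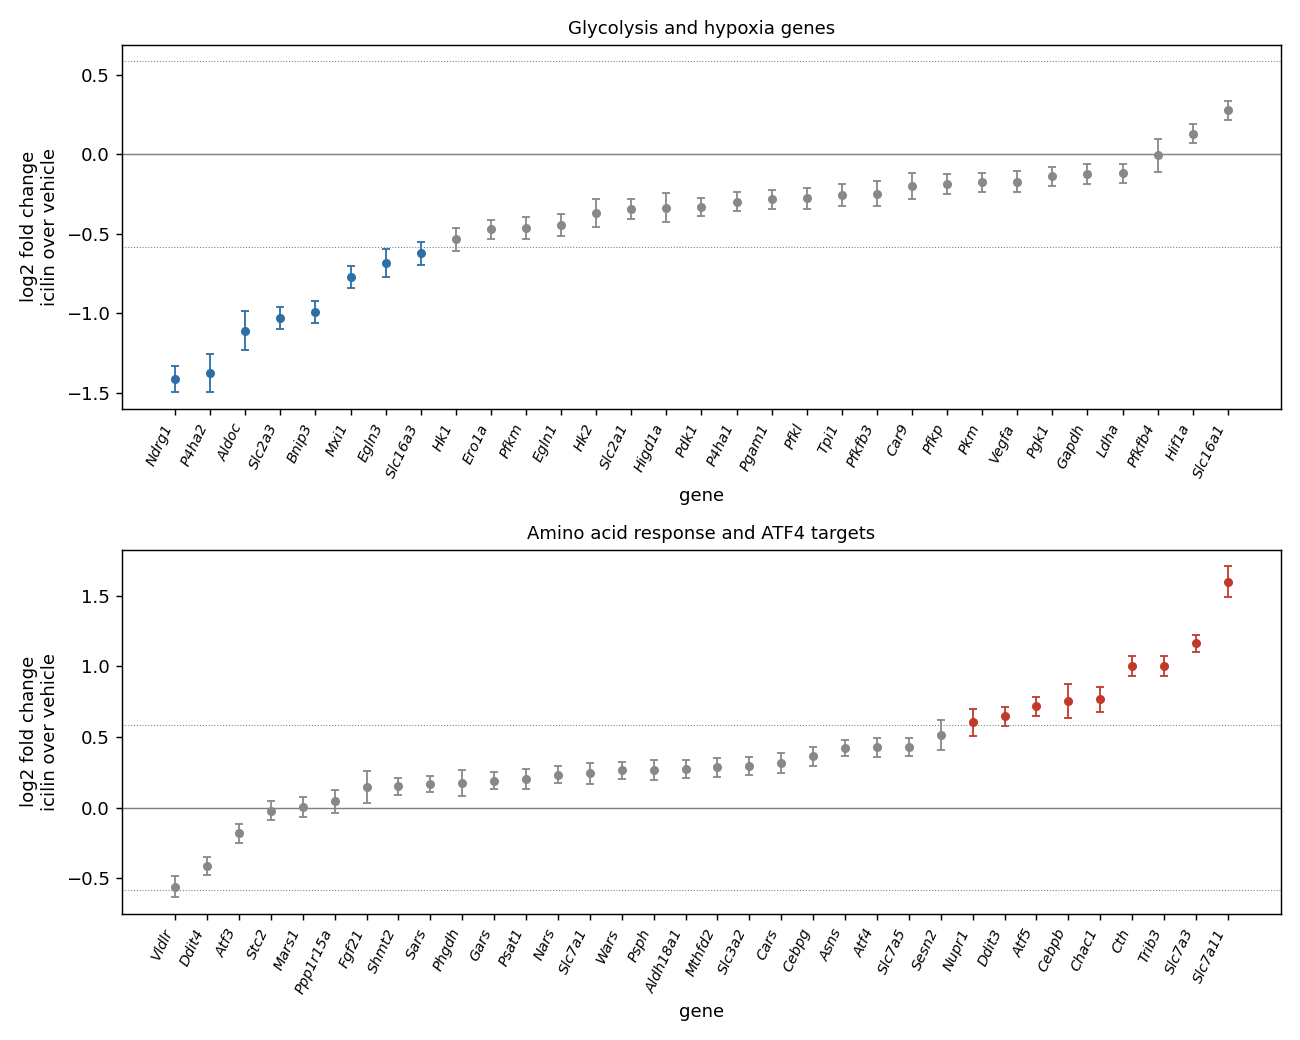
Log2 fold change (icilin minus vehicle, ± SE, 3 arrays per group) of each measured member of the glycolysis and hypoxia list and of the ATF4 target list, with dotted lines at 1.5-fold. Of the 31 glycolysis and hypoxia genes 29 lie below 0, and of the 34 ATF4 targets 30 lie above 0.

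Other stress response lists held fewer called genes, at most 2 each. For the unfolded protein response, limma called 0 of 25 genes, as did SAM, with 11 higher and 1 lower at an unadjusted p under 0.05; the list median was 0.18 (adjusted p = 0.000270 by camera; adjusted p = 0.140 with an estimated correlation). The chaperone gene Hspa5 had a difference of 0.20, and the oxidoreductase gene Ero1a, the member with the smallest p, one of -0.47 ± 0.06 (adjusted p = 0.00954), short of 1.5-fold. A second, dimmer probe set of Ero1a differed by -0.60, past 1.5-fold. Ero1a is also on the glycolysis and hypoxia list. Of 23 antioxidant genes regulated by NRF2, Slc7a11, which is also on the ATF4 list, rose and 22 did not pass. That list had a median of 0.07 and an adjusted p of 0.0291 by camera (adjusted p = 0.178 with an estimated correlation), and its call ended without icilin replicate 1, icilin replicate 3 or vehicle replicate 1 (median 0.06 to 0.11, adjusted p 0.0579 to 0.101) and with dim genes left out (median 0.09, adjusted p = 0.0823). Both metal-binding metallothionein genes Mt2 (-1.11 ± 0.17, adjusted p = 0.0184) and Mt1 (-0.99 ± 0.10) fell among 6 measured metal response genes, whose median was -0.34 (adjusted p = 0.00219 by camera; adjusted p = 0.224 with an estimated correlation). For 16 heat shock genes limma and SAM called 0, 4 were higher and 1 lower at an unadjusted p under 0.05, and the heat shock protein gene Hspa1a had a difference of -0.38 (adjusted p = 0.0278). Among 22 p53 targets the cell cycle inhibitor gene Cdkn1a fell (-0.84 ± 0.08), and among 13 aryl hydrocarbon receptor targets the feedback regulator gene Tiparp fell (-0.83 ± 0.10). These 3 lists did not pass camera, with adjusted p of 0.497, 0.813 and 0.991.

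Genes of T cell activation and effector function changed in part. Of 25 activation and costimulation genes, the costimulatory receptor gene Tnfrsf9 (-1.02 ± 0.07, from 11.4 to 10.4) and the inhibitory receptor gene Ctla4 (-0.69 ± 0.06) fell and 23 did not pass, among them Il2ra (-0.04) and Cd69 (0.21), named after their values were seen. The list median was -0.13, with an adjusted p of 0.00219 by camera and an adjusted p = 0.140 with an estimated correlation. Of 21 Th1 and cytotoxic effector genes, 5 fell and 2 rose. The cytotoxic granule genes Gzma (-1.46 ± 0.08), Nkg7 (-0.85 ± 0.08), Gzmb (-0.76 ± 0.06) and Prf1 (-0.68 ± 0.10) and the regulator gene Runx3 (-0.81 ± 0.07) fell, while the chemokine receptor gene Cxcr3 (0.79 ± 0.07) and the transcription factor gene Eomes (0.67 ± 0.07) rose. Among 12 markers of natural killer and CD8 T cells, a list that also holds Eomes, 4 were lower and 2 higher at an unadjusted p under 0.05, and Crtam fell (-0.92 ± 0.16). Named after their values were seen, the Th1 regulator gene Tbx21 had a difference of 0.47 (adjusted p = 0.0191), short of 1.5-fold, and the cytokine gene Ifng one of -0.33 (adjusted p = 0.179). The Th1 list had a median of -0.08 (adjusted p = 0.00401 by camera; adjusted p = 0.140 with an estimated correlation).

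Of 13 Th2 genes, the cytokine genes Il24 and Il5 (-0.59 ± 0.12, adjusted p = 0.0513) fell and 11 did not pass, with a list median of -0.17 (adjusted p = 0.00367 by camera; adjusted p = 0.224 with an estimated correlation). The call of Il5 ended without icilin replicate 1, icilin replicate 3 or any 1 of the vehicle replicates (-0.63 to -0.49, adjusted p 0.125 to 0.162), and when arrays were centred on their median (-0.57) or quantile normalized (-0.56), where the fold was below 1.5. Of 15 Th17 genes 1 fell, Csf2, which encodes the cytokine GM-CSF (-1.03 ± 0.11, adjusted p = 0.00515). A second, dim probe set of Csf2 differed by 0.07, and the mean of both probe sets (-0.48) was below the fold limit. The Th17 list had a median of -0.15 (adjusted p = 0.0164 by camera; adjusted p = 0.171 with an estimated correlation). Ctla4 was the called gene among 18 regulatory T cell genes (adjusted p = 0.0881 by camera), and the lineage factor gene Foxp3, named after its value was seen, had a difference of 0.29 (adjusted p = 0.126). Among 18 naive and quiescence genes the interleukin 7 receptor gene Il7r rose (0.72 ± 0.07), with an adjusted p of 0.991 by camera for the list.

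**Figure D3:**
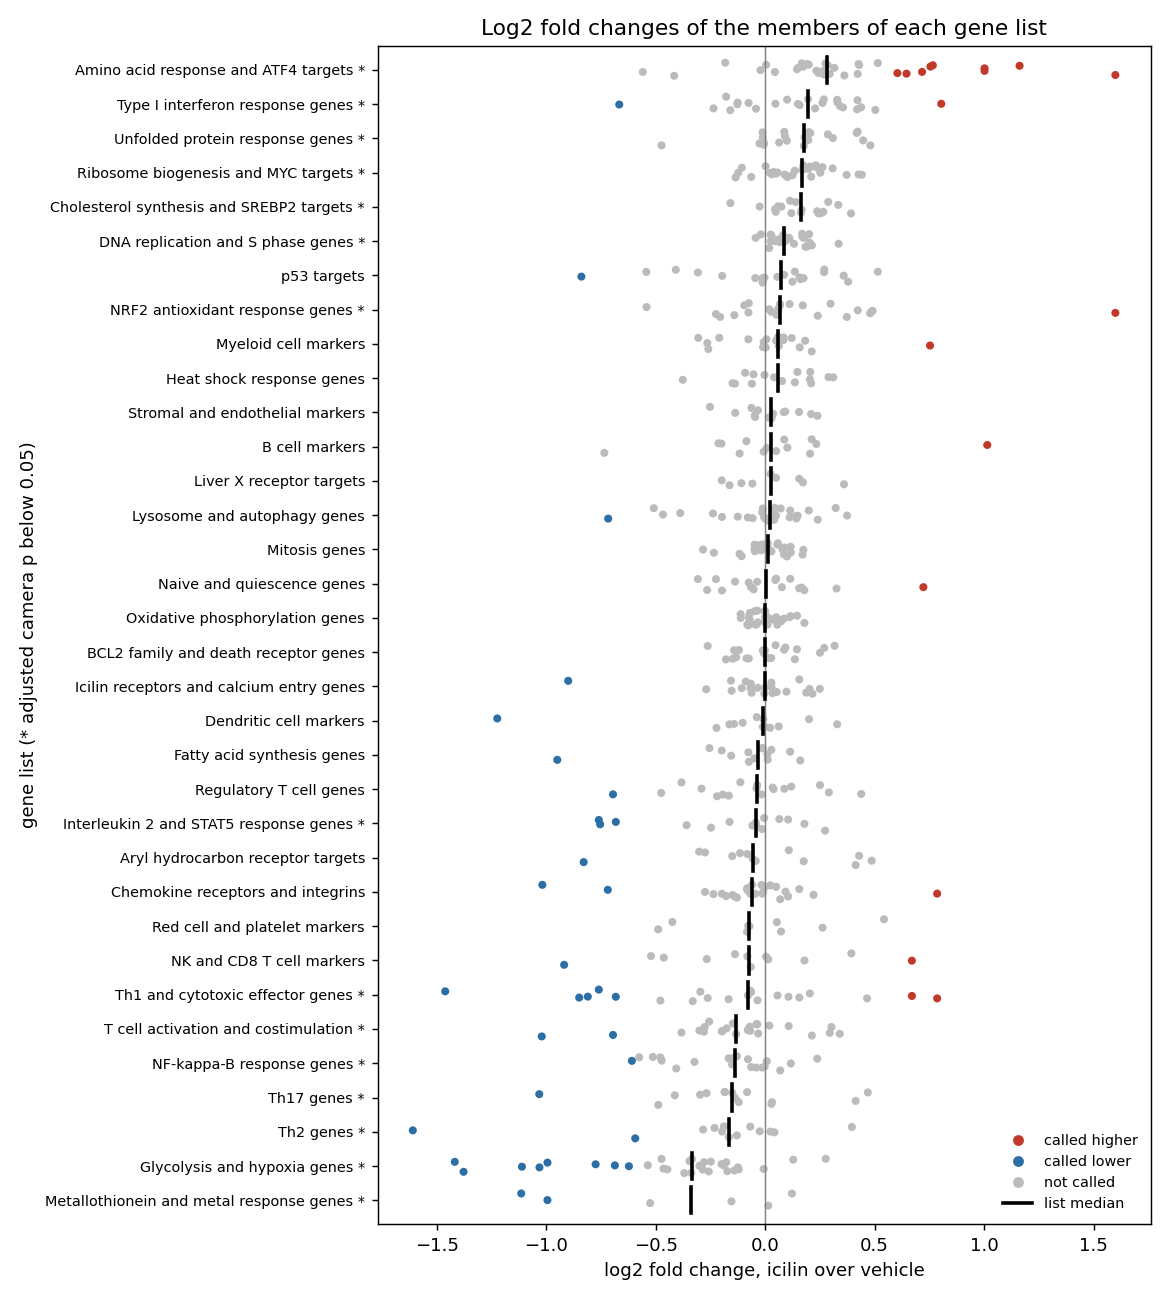
Log2 fold change (icilin minus vehicle) of the measured members of each gene list except the reference genes, with called genes in red (higher) or blue (lower), other genes in grey, a black bar at the list median and an asterisk at an adjusted p below 0.05 by camera. The glycolysis and hypoxia list (median -0.33) and the ATF4 target list (median 0.28) lie on opposite sides of 0.

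Signalling targets and migration receptors also held called genes. Of 15 targets of interleukin 2 and STAT5, Gzmb, Prf1 and the signalling inhibitor gene Socs3 (-0.75 ± 0.06) fell, with a list median of -0.04 (adjusted p = 0.00703 by camera; adjusted p = 0.204 with an estimated correlation). With the mean of its probe sets, Socs3 stood at -0.49, below the fold limit. Of 20 NF-κB targets the lymphotoxin gene Ltb fell (-0.61 ± 0.06) and 19 did not pass. Named after its value was seen, the NF-κB inhibitor gene Tnfaip3 had a difference of -0.58 (adjusted p = 0.0116). The NF-κB list median was -0.14 (adjusted p = 9.01e-05 by camera; adjusted p = 0.140 with an estimated correlation). The call of Ltb ended when arrays were centred on their median (-0.58). Of 27 chemokine receptor and integrin genes, Cxcr4, the receptor for CXCL12 (-1.02 ± 0.09), and the integrin gene Itgb3 (-0.72 ± 0.09) fell and Cxcr3 rose (adjusted p = 0.111 by camera for the list). Of 25 type I interferon response genes, Slfn1 rose (0.80 ± 0.11) and the RNA sensor gene Ifih1 fell (-0.67 ± 0.09, adjusted p = 0.0148), and the median was 0.20 (adjusted p = 0.0149 by camera; adjusted p = 0.204 with an estimated correlation). The call of Ifih1 ended without vehicle replicate 1 (-0.58), and that of the interferon list with dim genes left out (median 0.27, adjusted p = 0.0823).

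Among the lists of growth, lipid, cell death and organelle genes, Scd1 and Rragd were the called members. For ribosome biogenesis limma called 0 of 31 genes, as did SAM, with 16 higher at an unadjusted p under 0.05 and a median of 0.17 (adjusted p = 1.26e-05 by camera; adjusted p = 0.268 with an estimated correlation). The nucleolar protein gene Nop58 had a difference of 0.43 ± 0.07 (adjusted p = 0.0226). For DNA replication and S phase limma and SAM called 0 of 27 genes, 6 were higher at an unadjusted p under 0.05, and the median was 0.09 (adjusted p = 0.000521 by camera; adjusted p = 0.171 with an estimated correlation). The replication licensing gene Cdc6 stood at 0.34 ± 0.08 (adjusted p = 0.0956). For mitosis they called 0 of 28 genes, with 2 higher and 2 lower at an unadjusted p under 0.05, and the cyclin gene Ccnb2 at -0.28 (adjusted p = 0.0680). For cholesterol synthesis they called 0 of 19 genes, with 10 higher at an unadjusted p under 0.05, a median of 0.16 (adjusted p = 2.10e-05 by camera; adjusted p = 0.140 with an estimated correlation) and the sterol enzyme gene Hsd17b7 at 0.39 ± 0.07 (adjusted p = 0.0271). In fatty acid synthesis the desaturase gene Scd1 fell (-0.95 ± 0.09) among 14 genes (adjusted p = 0.124 by camera for the list). Among 29 lysosome and autophagy genes the GTPase gene Rragd fell (-0.72 ± 0.09), with an adjusted p of 0.991 by camera for the list. Liver X receptor targets (9 genes), BCL2 family and death receptor genes (21) and oxidative phosphorylation genes (31) each had 0 calls by limma and by SAM and an adjusted p of 0.991 by camera. At an unadjusted p under 0.05, the first held 1 higher and 1 lower gene, the second 3 higher and 1 lower and the last 0. Their members with the smallest p were Mylip (0.36, adjusted p = 0.156), the cell death gene Bcl2l11 (0.32, adjusted p = 0.0513) and Ndufab1 (0.18, adjusted p = 0.337).

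Markers of other cell types were also measured. On 6 such lists with 85 genes, of which 27 were brighter than the median gene and 2 were also on a T cell or pathway list, 3 rose and 2 fell. The B cell marker Ms4a1 rose by 1.01 ± 0.10 (list of 14 genes, adjusted p = 0.711 by camera), and adjusted over the list alone Ebf1, a B cell regulator named after its value was seen, also passed (-0.73). In the other 34 lists the counts adjusted over the list alone were those over all genes. Of 22 myeloid markers the gene Mpeg1, for a pore-forming protein, rose (0.75 ± 0.16, adjusted p = 0.0581), and its call ended without icilin replicate 1 or 3 or vehicle replicate 1 or 3 (0.63 to 0.76, adjusted p 0.152 to 0.163). Of 13 dendritic cell markers the MHC class II gene H2-Ab1 fell from 10.2 to 8.96 (-1.22 ± 0.08, adjusted p = 0.000927), while its partner H2-Aa stood at -0.04 and H2-Eb1 at -0.01, both named after their values were seen. Of 12 markers of natural killer and CD8 T cells, Eomes rose and Crtam, a receptor of activated cytotoxic cells, fell (-0.92 ± 0.16, adjusted p = 0.0311). The call of Crtam ended without icilin replicate 1 or 2 or vehicle replicate 2 or 3 (-0.93 to -0.82, adjusted p 0.107 to 0.116). Adjusted p by camera were 0.991 for the myeloid, 0.360 for the dendritic cell and 0.278 for the natural killer and CD8 list. Limma and SAM called 0 of 9 red cell and platelet markers (2 higher and 2 lower at an unadjusted p under 0.05; Car2 at 0.26; adjusted p = 0.940 by camera) and 0 of 15 stromal markers (0 at an unadjusted p under 0.05; Pdgfra at 0.24; adjusted p = 0.991 by camera). Of 12 reference genes they also called 0, with 0 at an unadjusted p under 0.05. The smallest p among the reference genes was that of the glycolytic gene Pgk1 (-0.14), which the glycolysis and hypoxia list also holds (adjusted p = 0.903 by camera for the reference list).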

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

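The test on markers of other cell types, in the account of the glycolysis and hypoxia genes, was chosen only after the result was seen. Probe sets outside the comparisons also carried differences between the groups: in a fit over every probe set, 67 of the 16010 with no gene symbol passed the limits used for genes (31 higher, 36 lower), and the largest changes were those of probe sets 17453819 (-2.93) and 17205569 (1.46). Of the 1814 probe sets with several symbols, 20 passed (5 higher, 15 lower).

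The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. Only the real split, 1 of the 10, gave as many called genes: it gave 311, 82 higher and 229 lower, and the highest of the other splits gave 0 in all, 0 higher and 0 lower by limma, with 777 to 998 genes at an unadjusted p under 0.05 against 3802 for the real split. SAM called 329 genes in the real split and at most 1 in another. The real split moved 15 gene lists, and the highest of the others 3, again 1 of 10. Every other split puts icilin and vehicle arrays into both arms. A difference between the groups then widens the spread within arms, which lowers the number of calls. The counts of the other splits therefore do not measure what chance alone would give.

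The glycolysis and hypoxia genes were lower with icilin, with a list median of -0.33. A scaling difference that depends on brightness would move other genes of the same brightness alike, but random lists matched on brightness had a typical median of 0.0225, 95% of them between -0.0364 and 0.0778. Loss of another cell type stays open, for lack of markers. B cells, myeloid cells, and natural killer and CD8 T cells each had fewer than 5 markers brighter than the median gene. The lowest median of the 6 types was -0.077 (red cell and platelet), and the highest 0.394 (natural killer and CD8, over 3 markers). Dendritic, red cell and stromal markers lay above the list median by more than their interquartile range. Single markers went both ways: H2-Ab1 (-1.22) and Crtam (-0.92) fell, and Ms4a1 (1.01), Mpeg1 (0.75) and Eomes (0.67) rose. H2-Aa, the partner of H2-Ab1, and H2-Eb1, another MHC class II gene, did not pass. At an unadjusted p under 0.05, 4 of 12 natural killer and CD8 markers were lower and 2 higher. Another candidate explanation is lower activity of hypoxia-inducible factor: 19 measured targets kept apart for this test had a median of -0.23, with 17 below 0, 0 called by limma or SAM and 11 lower at an unadjusted p under 0.05 (camera p = 3.66e-10; p = 0.00243 with an estimated correlation). Those 19 targets were listed after the main results, and the explanation was found and tested on the same arrays. Whether lower oxygen use, fewer live cells or a direct action of icilin stands behind the fall was not tested.

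Targets of ATF4 were higher, with a list median of 0.28. Random lists matched on brightness had a typical median of 0.0231, 95% of them between -0.0314 and 0.0757, which argues against a scaling difference of genes of that brightness. A candidate explanation, higher activity of ATF4, was tested on 21 targets kept apart from the first list. Those targets were listed after the main results. Their median was 0.21, with 17 above 0 and 0 called by limma or SAM. At an unadjusted p under 0.05, 12 were higher and 1 lower (camera p = 2.78e-06, and p = 0.0298 with an estimated correlation). This is consistent with a higher ATF4 activity, as a hypothesis found and tested on the same arrays. Whether amino acid supply, endoplasmic reticulum stress or another input differed was not tested, nor was a change in cell composition for this list.

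Guanylate-binding protein genes, chosen after Gbp10 was seen among the largest rises, had a median log2 fold change of 0.63 over 10 measured genes, and 5 rose. Signal shared between near-identical copies stays open: with Gbp10 itself left out, 4 of 5 measured genes in its genomic cluster rose (median 0.77), and in the other cluster limma and SAM called 0 of 4 (median 0.47), where 3 were higher at an unadjusted p under 0.05 and the same 3 passed the adjusted p short of 1.5-fold, and the difference between the clusters was not tested. Irgm2 and Igtp, GTPase genes of unrelated sequence with the same inducer, had a median of 0.52, which was to count against shared signal, but a rise elsewhere does not bear on how signal divides among the copies. A candidate biological explanation is a stronger response to interferon gamma, of which 36 other targets had a median of 0.0880, with 24 above 0, 0 called by limma or SAM, and 11 higher and 2 lower at an unadjusted p under 0.05 (camera p = 0.00996; p = 0.107 with an estimated correlation). Its own gene Ifng stood at -0.33 and did not pass. Those 36 targets were listed after the main results. The 25 measured type I interferon response genes had a median of 0.20, with 17 above 0 and 8 below. Which interferon response, if either, stands behind the rise was not tested.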

How the results depend on the processing

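All alternatives were planned. The count of 311 changed genes (82 higher, 229 lower) lay between 267 and 331 with a trend and robust variances (331), arrays centred on their median (303), quantile normalization (313), dim genes left out (267, of 11090 genes), probe sets averaged (302) and SAM (329, which held all 311), and with each array left out in turn it ran from 279 to 328. It was 358 over every probe set. By construction the limits moved it: 734 genes (268 higher, 466 lower; 91 list members) at an adjusted p under 0.05 with no fold limit, and 87 (18 and 69; 16 list members) with 2-fold. With the replicate block the counts were 283 (73 higher, 210 lower; 276 shared), 46 list members and 15 lists, and paired SAM called 312 genes; the block ended the calls of Il5 (adjusted p = 0.117; 0.00933 to 0.162 over its alternatives) and Mpeg1 (adjusted p = 0.15; 0.010 to 0.163). Same-numbered arrays had deviations that correlated at -0.02 to -0.01 across genes, others at -0.02 to 0.04, so the numbers do not show a pairing. The 15 list calls became 2 with an estimated correlation and 30 with fry in either direction, which tests another question. Of the 13 lists lost with an estimated correlation (adjusted p 0.140 to 0.268), 11 passed under all other alternatives with the preset correlation (2.04e-08 to 0.0414), and the type I interferon and NRF2 lists are described with their values. A higher correlation does not account for every loss. The Th1, Th17 and NRF2 lists had estimates of -0.0311, -0.0603 and -0.0271, below the preset 0.01. Their unadjusted camera p still rose, from 0.00126 to 0.0242, 0.00656 to 0.0440 and 0.0125 to 0.0509. The other lost lists had estimates of 0.0123 to 0.287. Another part of this setting also raises p. With an estimated correlation, camera takes p from a t distribution with the residual degrees of freedom, 4 here. With the preset correlation it uses far more degrees of freedom, so the same statistic gives a smaller p. How much each list lost to either part was not tested. Medians of lists that did not pass turned sign when arrays were centred on their median (BCL2 family 0.0247, calcium entry 0.0243, dendritic cell 0.0153), with quantile normalization (naive -0.00978, mitosis -0.00634, BCL2 family 0.0148, oxidative phosphorylation -0.0162, calcium entry 0.00750), with dim genes left out (naive -0.0441, aryl hydrocarbon receptor 0.414, calcium entry 0.0296, myeloid -0.0763, natural killer and CD8 0.394, stromal -0.0454, each over fewer genes) and with averaged probe sets (reference genes -0.00652). With single arrays left out, values that changed sign ranged from -0.0298 to 0.0132 (BCL2 family), -0.00691 to 0.0456 (calcium entry), -0.0158 to 0.0709 (liver X receptor), -0.00716 to 0.0346 (mitosis), -0.0138 to 0.0575 (myeloid), -0.00246 to 0.0517 (naive), -0.0286 to 0.0196 (oxidative phosphorylation), -0.125 to 0.0209 (red cell and platelet), -0.0229 to 0.0734 (stromal), -0.00426 to 0.0176 (reference genes), -0.178 to 0.0732 (Trpa1) and -0.0224 to 0.0379 (Trpm8). The cause was not tested. Named genes gave the same verdict in 1011 cases, lost the call in 49, gained it in 4 and turned sign in 6; list tests did so in 433, 18, 4 and 35. Genes dimmer than the median have no value with dim genes left out. On simulated arrays limma called 46.3% of genes changed by 1.5-fold, which is the fold limit itself, and 99.1% of those changed by 2-fold. Of the genes changed by 1.5-fold, 84.5% passed the adjusted p alone. The simulated noise was drawn independently for each gene and array, without a mouse or array effect, so these shares describe that setting.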

Other observations

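The genes of this part were picked after their values were seen, and they stand for no wider group. Plod2, a collagen lysyl hydroxylase gene (-1.38 ± 0.08), Hilpda, a lipid droplet gene (-1.21 ± 0.07), Gbe1, the glycogen branching enzyme gene (-1.17 ± 0.08), and Hif3a (-0.90 ± 0.15) fell. Of the 19 separate targets of hypoxia-inducible factor, limma and SAM called 0, with 11 lower at an unadjusted p under 0.05. Vegfa stood at -0.17 (adjusted p = 0.252) and did not pass. The cytokine gene Il3, a neighbour of Csf2, fell by 1.52 ± 0.17, from a log2 level of 4.45 to 2.93. Of 6 measured Fos and Jun genes, Fosl2 (-1.01 ± 0.07) and Junb (-0.63 ± 0.07) fell and 4 did not pass, with the same counts when arrays were centred on their median or quantile normalized. The signalling genes Malt1 (-0.91 ± 0.06) and Map3k8 (-0.72 ± 0.07) fell.

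Besides the guanylate-binding proteins, 6 of 8 measured immunity-related GTPase genes rose, with a median of 0.76, among them Gm4951 (1.24 ± 0.14), Gm4841 (1.03 ± 0.08), Iigp1 (0.90 ± 0.07) and Irgm1 (0.84 ± 0.08). Counts for both GTPase families were the same when arrays were centred on their median or quantile normalized. Of 20 measured Ms4a genes, 4 rose and 16 did not pass, with a median of 0.03 and 7 higher and 1 lower at an unadjusted p under 0.05. The 4 were Ms4a4b and Ms4a1 together with Ms4a4c (0.97 ± 0.09) and Ms4a6d (0.65 ± 0.14, adjusted p = 0.0568), and 5 rose when arrays were centred on their median. No test of the family as a whole was run.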
